A study of Mus musculus with 6 samples.

How the data were processed

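Gene expression was measured by RNA sequencing in 6 subcutaneous tumor libraries, 3 from PBS-injected and 3 from ATEV-injected tumors. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a stranded mRNA kit, which keeps the strand of each read. The submitters' processing notes name bcl2fastq 2.19, TopHat2 2.0.11 and Cufflinks 2.1.1, with no role or order. The program that counted the reads, its strand setting and its annotation release are not given in the sources used here. The deposited table holds raw whole-number read counts per gene, not normalized, for 42687 genes. The notes name the mouse build mm9, while 99% of the table's gene identifiers are found in GENCODE release M21, which belongs to a later build. The build behind the counts is therefore open and no coordinates are given. Gene symbols are those of the deposited table. Every entry names a gene, and the 6 value columns carry the library names of the 6 samples.

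Groups and replicate numbers came from the sample labels. Before any averaging, libraries were compared in pairs. The smallest chi-square per degree of freedom over genes was 29.8, so no pair agreed within sampling noise. By this measure PBS 2 and PBS 3 were closer to ATEV 2 (52.8 and 64.7) than to each other (85.4). PBS 1 was closest to PBS 2 (302.8), and each ATEV library was closest to another ATEV library. Total counts ran from 15319740 to 28921256, and the biological coefficient of variation was 0.368.

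Genes were kept with the default filter of edgeR (minimum count 10, minimum total count 15), which left 14731. Library sizes were scaled by TMM, and ATEV was compared with PBS by edgeR's quasi-likelihood test with robust dispersion (edgeR 4.0.16, R 4.3.3), without covariates. P-values were adjusted by Benjamini-Hochberg over all genes tested and the threshold was 0.05. The standard error of a log2 fold change was computed as its size divided by the square root of the F statistic, an approximation. CPM values are counts scaled to library size with TMM factors, given as mean ± SD over 3 libraries. Antisense and overlapping genes and near-identical paralogs remain uncertain, since the counting settings are not stated.

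Before the data were examined, 45 gene lists with 654 entries were fixed, covering antigen presentation, interferon responses, immune and stromal cell types, tumor epithelium, signaling and metabolic programs, other tissues that a subcutaneous tumor piece can hold, and signs of RNA quality. Of these, 43 had at least 3 tested members. Each was tested by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, adjusted over the lists. Camera asks whether a list moved relative to all other genes. The same test with an estimated correlation and fry, which asks whether a list moved at all, were alternatives. None of the 18 lists past the preset test passed with an estimated correlation, and 5 lists passed by fry (T cells, macrophages and monocytes, mast cells with basophils and eosinophils, extracellular matrix, and endothelial cells). Counts "adjusted over the list alone" used Benjamini-Hochberg within the list.

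Also fixed beforehand was the rule for the genes named. It took the 10 largest log2 fold changes in each direction among genes past the threshold with non-overlapping groups and a mean log2 CPM of at least 1, leaving out predicted genes and immunoglobulin and T cell receptor segments. Where fewer than 5 passed in a direction, it took the 5 with the smallest p, named as not past. It further took up to 4 members with the smallest p of each list past its test or with a member past the threshold, up to 2 members of other lists, and always 18 genes, of which 1 is not used here (H2-K1, B2m, H2-Ab1, Cd274, Cd8a, Cd4, Foxp3, Gzmb, Prf1, Ifng, Cxcl9, Cxcl10, Ifnb1, Krt19, Mki67, Arg1 and S100a8). Which of the lists that did not pass had their medians and members described, and which of the up to 4 members of a list were named, was narrowed after their values were seen. After the data were seen, 8 more lists were written for the closing section: broad epithelial, broad leukocyte, classical-type and basal-type pancreatic cancer, stomach, liver and intestine genes, and trypsins with acinar genes.

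The tests were checked on simulated counts for the 14731 genes, drawn from the means and library sizes of these libraries with known changes. For the ATEV and PBS comparison edgeR recovered 2.985% of genes changed 2-fold, 68.66% of those changed 4-fold and 100% of those changed 16-fold, with 6 false calls. DESeq2 recovered 19.4%, 86.57% and 100% with 30 false calls. The known changes were put only into genes with a mean over 2 CPM, and no trend with transcript length was put in. The recovered shares and false calls hold for that setting only. Among such genes, changes near 2-fold are therefore mostly missed by the main test at this depth and number of libraries.

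The alternatives tried were RLE, total count and upper-quartile scaling, no low-count filter and a stricter one (at least 1 CPM in 3 libraries), DESeq2 1.42.0, voom with and without quality weights, a looser threshold of 0.1, each library left out in turn, and the replicate number as a block. Added after the data were seen were corrections for transcript length alone or with GC content (longest GENCODE M21 transcript of each gene, smooth trend per library by mgcv 1.9.3, passed to edgeR as offsets), a table without ribosomal protein genes and Gm42418, a fit without PBS 1 and ATEV 1, and the list test under total count and upper-quartile scaling. A length was found for 14702 of the genes tested.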

Results

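The series measured gene expression by bulk RNA sequencing in subcutaneous pancreatic tumors of female C57BL/6 mice. The tumors grew from clone 6419c5 of KPCY, a mouse pancreatic cancer line with mutant Trp53 and a yellow fluorescent protein reporter. Tumors were injected with phosphate-buffered saline (PBS, 3 libraries) or with a preparation that the labels call ATEV (3 libraries), given as 25 µg carrying 10 µg of DNA named EVDNA. The labels do not spell out ATEV, and the series title and its design text differ on whether the clone is immunogenic. Each injection held 30 µL, and 6 injections were given 3 days apart, starting 4 days after inoculation, with harvest 9 days after the last one. The comparison asks what the injected ATEV did to the tumor transcriptome. Total counts were 28921256, 18651977 and 16778297 in PBS replicates 1, 2 and 3, and 18796479, 20311272 and 15319740 in ATEV replicates 1, 2 and 3.

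ATEV tumors held far more transcript of a small group of genes than PBS tumors, among them 3 gastrokine genes and 2 trefoil factor genes, which encode secreted proteins of the stomach lining. As groups, genes of antigen presentation, of interferon responses and of several immune cell types were higher in ATEV tumors. Genes of the extracellular matrix, of blood vessels and of mesenchymal cells were lower as groups. These group results came from a test with a preset correlation between genes, and none of them passed when that correlation was estimated.

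Among the genes past the threshold, the one with the largest fold change, Gkn2 (ENSMUSG00000030049), encodes a gastrokine, a secreted protein of the stomach lining. It was counted 5, 0 and 6 times in the PBS libraries and 568, 261 and 325 times in the ATEV libraries, a log2 fold change of 7.04 ± 0.80 (SE, n = 3 per group, adjusted p = 0.0305, edgeR). Tff2 (ENSMUSG00000024028), a trefoil factor secreted with mucus, rose from 5.18 ± 1.23 CPM in PBS to 176 ± 55.7 CPM in ATEV tumors (SD, n = 3), a log2 fold change of 5.10 ± 0.39 (SE, adjusted p = 0.00909). In all, 38 of 14731 genes tested were higher in ATEV tumors and 2 were lower at an adjusted p under 0.05. Every one of these 40 genes had all 3 ATEV values on one side of the 3 PBS values, which 28.1% of all genes tested also did and chance gives in 10%.

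The other gastrokines rose as well. Gkn1 went from 3.33 ± 1.56 to 73.2 ± 35.4 CPM and Gkn3 from 0.716 ± 0.397 to 18.0 ± 9.03 CPM (SD, n = 3), log2 fold changes of 4.48 ± 0.57 and 4.71 ± 0.61 (SE). Tff1, another trefoil factor, rose by 3.37 ± 0.43 on the log2 scale. Further genes past the threshold had other functions. Gsta3 (ENSMUSG00000025934), a glutathione transferase, rose by 5.16 ± 0.56 (1.76 ± 1.09 to 62.4 ± 25.1 CPM), and the cytochrome P450 gene Cyp2c55 by 5.63 ± 0.79. The cystine transporter subunit gene Slc7a9 rose by 4.08 ± 0.53 and the proline-rich acidic protein gene Prap1 by 5.26 ± 0.65. Serpina1c, of the alpha-1-antitrypsin family, rose by 4.44 ± 0.59, but its near-identical copies make its count uncertain. Ccl20, the chemokine ligand of CCR6, rose by 3.35 ± 0.49 (adjusted p = 0.0416). It was the 1 member of the fixed NF-kB target list past the threshold, and that list did not pass its set test.

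The 2 lower genes were Try5 and Prg4. Try5 (ENSMUSG00000036938), a trypsin gene whose reads may be shared with its paralogs and whose count is uncertain for that reason, stood at 80.3 ± 27.5 CPM in PBS and 17.8 ± 1.23 CPM in ATEV tumors, a log2 fold change of -2.17 ± 0.31 (SE, adjusted p = 0.0407). Prg4 (ENSMUSG00000006014), which encodes the joint lubricant lubricin, stood at 13.1 ± 6.62 and 1.68 ± 0.393 CPM, a log2 fold change of -2.95 ± 0.45 (adjusted p = 0.049). The next genes by p did not pass. Olr1, a receptor for oxidized lipoprotein, had a log2 fold change of -1.89 ± 0.30 (adjusted p = 0.0509), the casein gene Csn3 of -3.52 ± 0.55 (adjusted p = 0.051) and the pentraxin gene Nptx1 of -2.94 ± 0.49 (adjusted p = 0.0556).

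**Figure D1:**
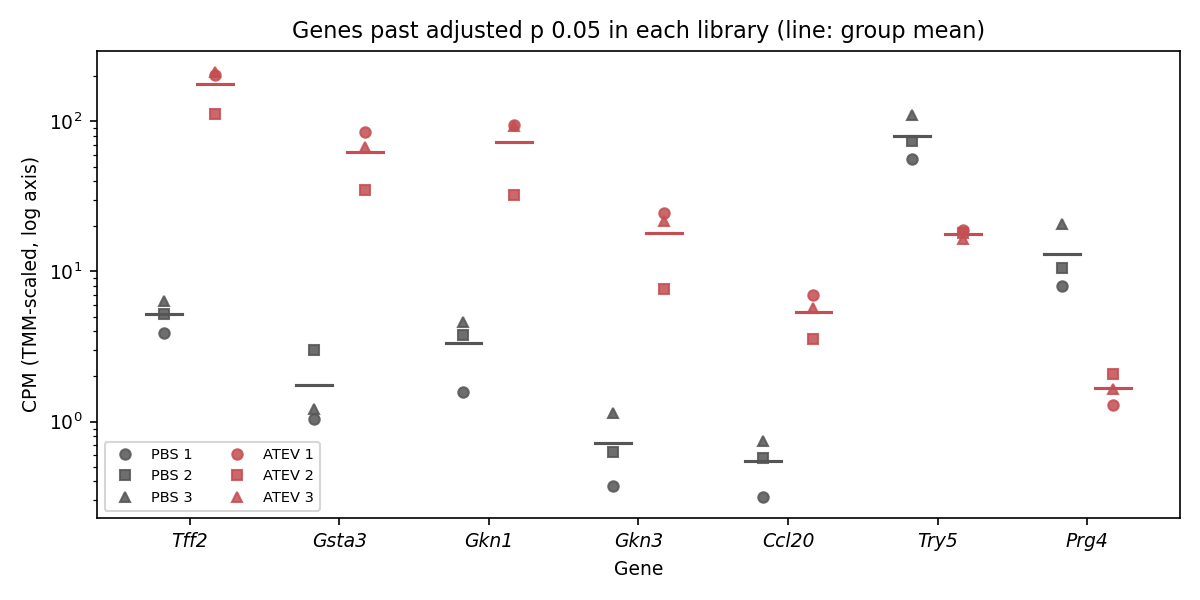
CPM (log axis) of 7 genes past adjusted p 0.05 in each of the 6 libraries, PBS in grey and ATEV in red, with the group mean as a line. In each gene the 3 ATEV values lie on one side of the 3 PBS values, above them in Tff2, Gsta3, Gkn1, Gkn3 and Ccl20 and below them in Try5 and Prg4.

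The counts of higher and lower genes depended on single libraries. By edgeR they were 128 and 31 without PBS 1, 231 and 385 without PBS 3, and 23 and 0 without ATEV 2, while leaving out PBS 2, ATEV 1 or ATEV 3 left no gene past the threshold, with 2363, 1667 and 1625 genes at an unadjusted p under 0.05. All 38 genes kept their direction and an unadjusted p under 0.05 in each of these fits. DESeq2 called 553 genes higher and 580 lower. By edgeR 3002 genes had an unadjusted p under 0.05, where 737 would by chance if p-values were evenly spread. But PBS 1, PBS 2 and ATEV 2 set against the other libraries, a split that mixes the groups, gave 2496 such genes. The excess over 737 is therefore not by itself an effect of ATEV. Nothing in the labels says that each library came from a different mouse, so the p-values measure only the spread between these samples.

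Genes of antigen presentation were higher in ATEV tumors as a group. The list of MHC class I presentation had a median log2 fold change of 1.43, with 17 of 18 members positive (camera, adjusted p = 2.36e-06; adjusted p = 0.425 with an estimated correlation). None of the 18 passed over all genes tested and 12 were higher when adjusted over the list alone. The same 0 over all genes held for each of the other lists past the test except that of ductal tumor epithelium. The immunoproteasome genes Psmb8 and Psmb9 had log2 fold changes of 2.67 ± 0.42 (SE, adjusted p = 0.0515) and 2.54 ± 0.51 (adjusted p = 0.0802), and the heavy chain gene H2-K1, which has close paralogs, of 1.51 ± 0.44 (adjusted p = 0.16). The light chain gene B2m had 1.40 ± 0.44 (adjusted p = 0.172), and 0.20 after correction for transcript length and GC content. The MHC class II list had a median of 1.35, with 10 of 10 tested members positive and 2 higher when adjusted over the list alone (adjusted p = 0.000102; 0.425 as adjusted p with an estimated correlation). Among them H2-DMb1, a peptide-loading chaperone gene, had 2.28 ± 0.38 (adjusted p = 0.0531), the protease gene Ctss 1.04 ± 0.26 and H2-Ab1 1.39 ± 0.47. Ctss had 0.27 after correction for length and GC, and H2-Ab1 0.66 with length alone corrected. The class II median was 2.22 without PBS 1, 0.66 with length alone corrected and 1.06 with length and GC corrected.

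Interferon-response lists were higher too. The type I list had a median log2 fold change of 1.37, 22 of 23 members positive (camera, adjusted p = 1.09e-07; adjusted p = 0.425 with an estimated correlation), and 13 higher when adjusted over the list alone. Cmpk2 had 2.97 ± 0.55 (SE, adjusted p = 0.0711), the antiviral gene Oas1a 2.44 ± 0.48 and Rsad2, which encodes viperin, 2.15 ± 0.51. The interferon-gamma list had a median of 1.07, 21 of 23 members positive (adjusted p = 4.18e-06; adjusted p = 0.434 with an estimated correlation), and 15 higher when adjusted over the list alone. The guanylate-binding protein genes Gbp5 and Gbp4 had 1.63 ± 0.41 and 2.24 ± 0.65, the T cell chemokine genes Cxcl9 and Cxcl10 2.54 ± 0.88 and 1.83 ± 0.59 (1.54 and 1.04 without ATEV 3), and Cd274, the gene of PD-L1, 1.07 ± 0.35 (adjusted p = 0.18). The cytosolic DNA sensing list did not pass (median 0.22, adjusted p = 0.0563; 0.0323 to 0.425 over all alternatives), but it passed without PBS 2 (0.31, adjusted p = 0.0323), without ATEV 1 (0.16, adjusted p = 0.0419) and without both PBS 1 and ATEV 1 (0.30, adjusted p = 0.0462). It also passed with the stricter low-count filter (0.24, adjusted p = 0.0469) and with length corrected (0.30, adjusted p = 0.0433), but not with length and GC corrected (0.24, adjusted p = 0.19), and its median was 0.37 without ATEV 2. Its members with the smallest p were Mndal, at 1.74 ± 0.46 (0.95 with length and GC corrected), and Zbp1, at 1.48 ± 0.51. Ifnb1, with 30 counts over the 6 libraries, was under the filter on low counts, at 0.127 ± 0.164 CPM in PBS and 0.496 ± 0.651 CPM in ATEV tumors (SD, n = 3).

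Markers of several immune cell types were higher. The T cell list had a median log2 fold change of 1.17, 11 of 12 tested members positive and 2 higher when adjusted over the list alone (camera, adjusted p = 0.000931; adjusted p = 0.395 with an estimated correlation). Cd3d, of the T cell receptor complex, stood at 0.317 ± 0.290 CPM in PBS and 4.68 ± 2.41 CPM in ATEV tumors (SD, n = 3), a log2 fold change of 4.03 ± 0.84 (SE, adjusted p = 0.0861). Cd3g had 2.90 ± 0.61, the kinase gene Lck 1.25 ± 0.42 and Cd4 1.09 ± 0.59 (adjusted p = 0.315), or 2 without PBS 1. Cd8a, with 100 counts in all, was under the low-count filter at 0.102 ± 0.102 and 1.84 ± 1.26 CPM. Without that filter its log2 fold change was 4.34 ± 0.89 (adjusted p = 0.00411). That fit called 387 genes higher and 353 lower, so its adjusted p cannot be set beside those of the main fit. Foxp3 and Ifng had 21 and 10 counts in all, too few to be tested. Foxp3 stood at 0.211 ± 0.192 CPM in PBS and 0.0504 ± 0.0468 CPM in ATEV tumors, and Ifng at 0.0269 ± 0.026 and 0.166 ± 0.115 CPM. Without the filter their log2 fold changes were -1.96 ± 1.29 and 2.24 ± 1.46 (adjusted p = 0.452 and 0.447). The cytotoxic effector list had a median of 1.05, 12 of 14 positive and 1 higher when adjusted over the list alone (adjusted p = 0.000931; adjusted p = 0.555 with an estimated correlation). Its median was 0.63 without PBS 1 and 0.38 with length and GC corrected. The chemokine gene Xcl1 had 3.66 ± 0.79, the granzyme gene Gzmb 1.08 ± 0.44 (0.55 with length and GC corrected) and the perforin gene Prf1 0.43 ± 0.40 (adjusted p = 0.516), which ran from 0.17 without ATEV 2 to 0.70 without PBS 3.

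The macrophage and monocyte list had a median log2 fold change of 0.85, 14 of 18 members positive and 8 higher when adjusted over the list alone (camera, adjusted p = 0.000313; adjusted p = 0.395 with an estimated correlation). The Fc receptor gene Fcgr1 had 1.82 ± 0.35 (SE, adjusted p = 0.0728), Trem2 1.47 ± 0.39 (0.95 without both PBS 1 and ATEV 1) and Adgre1, the gene of F4/80, 0.88 ± 0.28. The list of mast cells, basophils and eosinophils had a median of 1.5, with 7 of 11 positive and the same number higher when adjusted over the list alone (adjusted p = 0.0054; adjusted p = 0.395 with an estimated correlation). Siglecf, an eosinophil receptor gene, had 2.72 ± 0.59 and the mast cell protease gene Cpa3 1.92 ± 0.45, or 1.11 with length and GC corrected. The neutrophil list had a median of 1.03, with 10 of 12 positive and 1 higher when adjusted over the list alone (adjusted p = 0.00452; adjusted p = 0.571 with an estimated correlation), and without PBS 1 it was 0.73 and no longer passed (adjusted p = 0.104; 0.000386 to 0.571 over all alternatives). With length and GC corrected the neutrophil median was 0.60 and passed (adjusted p = 0.029). Il1r2 had 1.36 ± 0.35 (0.85 in that correction) and S100a8 1.39 ± 0.75, which was 0.87 without PBS 1, 2.21 without PBS 2 and 0.59 with length and GC corrected. The complement list had a median of 0.74, 12 of 14 positive and 0 when adjusted over the list alone (adjusted p = 0.0101; adjusted p = 0.425 with an estimated correlation). C1qb had 1.04 ± 0.31 (0.35 with length corrected) and Serping1, the C1 inhibitor gene, -1.32 ± 0.40. Without PBS 3 the complement list did not pass (median 0.63, adjusted p = 0.108; 0.0014 to 0.425 over all alternatives). Arg1, expressed by suppressive myeloid cells, had 1.05 ± 0.47 (adjusted p = 0.252), or 0.66 without PBS 1 and 0.59 with length and GC corrected.

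Genes of the extracellular matrix and of blood vessels were lower in ATEV tumors as groups. All 21 members of the matrix list had negative fold changes, with a median log2 fold change of -1.04 (camera, adjusted p = 1.09e-07; adjusted p = 0.395 with an estimated correlation), and 16 were lower when adjusted over the list alone. Vcan, the proteoglycan versican, had -1.07 ± 0.26 (SE, adjusted p = 0.11), the basement membrane collagen genes Col4a1 and Col4a2 -1.81 ± 0.50 and -2.39 ± 0.63, and Col5a1 -1.5 ± 0.42. With length and GC corrected these 3 collagen genes had -0.66, -1.07 and -0.38 and Vcan -0.54, and without PBS 1 Col4a1 had -1.20. With length and GC corrected the matrix median was -0.47 (adjusted p = 0.00298; 1.3e-09 to 0.395 over all alternatives). The endothelial list had a median of -0.95, 12 of 14 negative and 6 lower when adjusted over the list alone (adjusted p = 0.000102; adjusted p = 0.395 with an estimated correlation). The vascular growth factor receptor gene Flt1 had -1.37 ± 0.32 and Cdh5, vascular cadherin, -1.28 ± 0.32. With length and GC corrected Flt1 had -0.73 and the endothelial median was -0.62 (adjusted p = 0.0048; 1.39e-07 to 0.395 over all alternatives). The list of mesenchymal and EMT genes had a median of -0.77, 13 of 13 negative and 0 when adjusted over the list alone (adjusted p = 0.00221; adjusted p = 0.425 with an estimated correlation). Twist1 had -1.20 ± 0.32, the fibronectin gene Fn1, also in the matrix list, -1.68 ± 0.51 and Mmp14 -1.64 ± 0.52. Fn1 had -0.79 with length and GC corrected, and Mmp14 had -1.02 without PBS 1.

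Fibroblast markers had a median log2 fold change of -0.41, with 13 of 16 negative (camera, adjusted p = 0.0368; adjusted p = 0.425 with an estimated correlation). Adjusted over the list alone 5 were lower and 1 was higher. Pdgfra had -1.29 ± 0.28 (SE, adjusted p = 0.0901), Fbln2 -1.28 ± 0.38 and Dpt 1.36 ± 0.43. With length and GC corrected Pdgfra had -0.80 and Fbln2 -0.65, and Dpt had 0.84 without both PBS 1 and ATEV 1. This list did not pass without PBS 2 (-0.42, adjusted p = 0.0833), PBS 3 (-0.09, adjusted p = 0.179) or ATEV 2 (-0.22, adjusted p = 0.214), nor with length and GC corrected (adjusted p = 0.0739), and its adjusted p ran from 0.000566 to 0.425 over all alternatives. The TGF-beta target list had a median of -0.54, with 11 of 12 negative and 1 lower when adjusted over the list alone (adjusted p = 0.0163; adjusted p = 0.425 with an estimated correlation). Thbs1, an extracellular glycoprotein gene, had -1.46 ± 0.35 and Tgfb1 -1.46 ± 0.49, or -0.85 without PBS 1. The list did not pass without PBS 2 (-0.39, adjusted p = 0.0505) or PBS 3 (-0.61, adjusted p = 0.056), nor with length and GC corrected (-0.30, adjusted p = 0.1), with 0.00196 to 0.425 over all alternatives.

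The list of pancreatic ductal tumor epithelium had a median log2 fold change of 0.42, 13 of 20 members positive (camera, adjusted p = 0.0163; adjusted p = 0.425 with an estimated correlation). The members past the threshold over all genes were the trefoil genes Tff2 and Tff1, which encode secreted mucosal peptides, and adjusted over the list alone 5 were higher and 1 lower. The claudin gene Cldn7 had 3.50 ± 0.65 (SE, adjusted p = 0.0707), the galectin gene Lgals4 2.24 ± 0.46 and the duct keratin gene Krt19 0.83 ± 0.34 (adjusted p = 0.228), or 0.39 with length corrected. Without PBS 3 the list did not pass (median 0.37, adjusted p = 0.173; 0.00118 to 0.425 over all alternatives). Proliferation genes as a list were not moved in one direction (median 0.02, 12 of 24 positive, adjusted p = 0.596), and the median was -0.11 under total count scaling. The cycling marker gene Mki67 had -1.21 ± 0.49 (adjusted p = 0.227) and the replication gene Mcm2 -1.07 ± 0.42. Without PBS 1 these genes had -0.45 and -0.47, and Mki67 had -0.50 with length and GC corrected. The list median was 0.34 without PBS 1 and -0.33 without PBS 2.

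Lists of other tissue and of library composition passed as well. Skeletal muscle genes had a median log2 fold change of -1.74 (camera, adjusted p = 0.0296; adjusted p = 0.715 with an estimated correlation), with 19 of 21 negative and 0 when adjusted over the list alone. Their mean log2 CPM was 1.91, -0.96 and 2.82 in PBS 1, 2 and 3 and -1.42, 1.55 and -0.54 in ATEV 1, 2 and 3, so that the groups overlapped. The muscle list did not pass without PBS 3 (-0.79, adjusted p = 0.664), ATEV 1 (-1.21, adjusted p = 0.111) or ATEV 3 (-1.25, adjusted p = 0.0793), and its median was -4.23 without ATEV 2. Over all alternatives its adjusted p ran from 1.61e-06 to 0.715. Actn3 had -3.71 ± 0.91 (-1.91 by voom with quality weights) and Casq1 1.19 ± 0.45. Ribosomal protein genes had a median of 0.32, 23 of 24 positive and 0 when adjusted over the list alone (adjusted p = 0.0104; adjusted p = 0.715 with an estimated correlation), with Rps27 at 0.90 ± 0.63, or 0.45 without PBS 1 and 1.38 without PBS 3. This median was 0.06 without PBS 1 (adjusted p = 0.832), 0.78 without PBS 3 and 0.07 with length and GC corrected (adjusted p = 0.494; 0.000432 to 0.978 over all alternatives). Ribosomal protein genes took 5.23% of the counts in PBS 1 and 14.89% to 19.2% in the other libraries.

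The remaining 25 lists tested did not pass, with adjusted p from 0.0508 to 0.996. Of the immune lists, B and plasma cells had a median log2 fold change of 1.84 over 4 tested genes (adjusted p = 0.105), tertiary lymphoid chemokines 0.93 over 3 genes (adjusted p = 0.0508), regulatory T cells 0.76 without the untested Foxp3 (adjusted p = 0.109), NK cells 0.70 (adjusted p = 0.162) and checkpoint and exhaustion genes 0.31 (adjusted p = 0.198). Their members with the smallest p were Ighm at 3.01 ± 0.81, Ltb at 2.31 ± 0.87, Tnfrsf18 at 1.97 ± 0.48, Klrb1c at 2.16 ± 0.54 and, in the checkpoint list, Cd274, followed by Ctla4 at 1.65 ± 0.56. Single libraries moved several of these values. Without ATEV 2 the B and plasma cell median was 0.87 and Ighm had 1.68, and without PBS 1 the NK cell median was 0.26 and Ltb had 4.86. Without PBS 3 the NK cell median was 1.23. Without PBS 2 the checkpoint median was 0.20. With length and GC corrected the medians of NK cells, regulatory T cells and checkpoint genes were 0.40, 0.49 and 0.11.

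Some of the 25 passed with 1 library left out, by camera. Without ATEV 3 these were B and plasma cells (2.21, adjusted p = 0.0161; 0.0161 to 0.434 over all alternatives) and tertiary lymphoid chemokines (1.24, adjusted p = 0.049; 0.0285 to 0.425). Without ATEV 1 regulatory T cells passed (0.89, adjusted p = 0.0267; 0.0212 to 0.549), and checkpoint and exhaustion genes passed without PBS 1 (0.38, adjusted p = 0.0458) or ATEV 1 (0.35, adjusted p = 0.0495), with 0.0141 to 0.571 over all alternatives. Chemokines and inflammatory cytokines passed without PBS 2 (adjusted p = 0.0251; 0.0251 to 0.921), myofibroblasts and pericytes without PBS 1 (adjusted p = 0.0152; 0.0152 to 0.571), and cholesterol synthesis without PBS 2 (adjusted p = 0.0241) or ATEV 1 (adjusted p = 0.0419), with 0.0241 to 0.715 over all alternatives. The other lists of the 25 were costimulation and dendritic cell activation, conventional and plasmacytoid dendritic cells, immunosuppressive myeloid genes, p53 targets and apoptosis, hypoxia and glycolysis, oxidative phosphorylation, the unfolded protein response, NF-kB targets, skin keratinocytes, adipocytes, erythrocytes and blood, Schwann cells and nerve, immediate early genes, and replication-dependent histone genes, besides cytosolic DNA sensing and proliferation. Without both PBS 1 and ATEV 1 regulatory T cells (0.98, adjusted p = 0.0212), checkpoint and exhaustion genes (0.42, adjusted p = 0.0141) and myofibroblasts and pericytes (-0.38, adjusted p = 0.023) passed too. Tertiary lymphoid chemokines passed with RLE scaling (0.94, adjusted p = 0.0491) and with length and GC corrected (1.08, adjusted p = 0.0422). No Y-linked or mitochondrially encoded gene was tested.

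**Figure D2:**
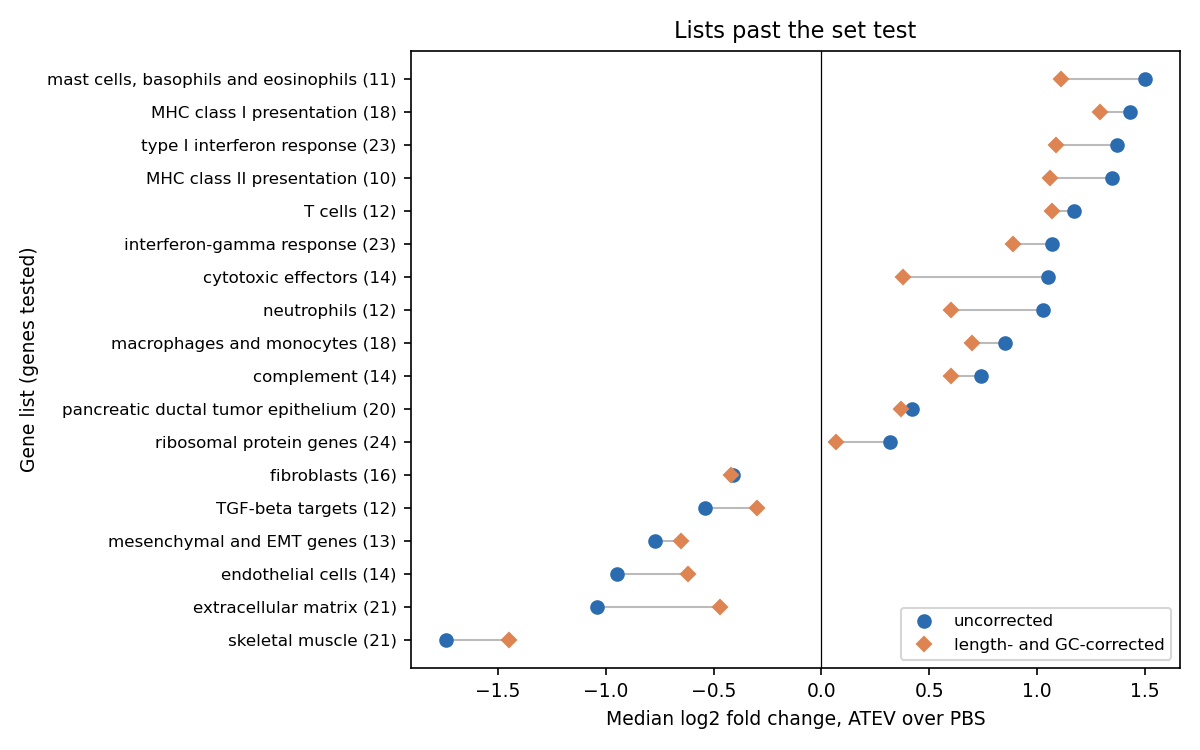
Median log2 fold change (ATEV over PBS) of the 18 lists past the set test, with the number of genes tested in brackets, uncorrected (circles) and with each library's transcript length and GC trends taken out (diamonds). The 12 higher lists and the 6 lower lists keep their sign, while the matrix median goes from -1.04 to -0.47 and the ribosomal protein median from 0.32 to 0.07.

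The libraries also differed in how counts were spread over short and long transcripts. Transcripts of up to 1000 nt lay at a median of -1.21 (log2) from their mean over the 6 libraries in PBS 1, and those over 6000 nt at 0.75 in PBS 1 and -0.59 in ATEV 1. Across 14702 genes the log2 fold change had a Spearman correlation of -0.43 with transcript length, where genes are not independent replicates. With the length and GC trends of each library taken out, a correction chosen after the data were seen, 255 genes were higher and 126 lower, among them all 38 higher and both lower genes. Of the 18 lists, 15 passed in the same direction by camera with the preset correlation, and none passed in that fit with an estimated one (lowest adjusted p = 0.503). In that fit 5 genes of the MHC class I list and 3 of the type I interferon list were higher over all genes, and 0 were lower. Among them was Psmb8 at 2.46 (adjusted p = 0.0139, and 2.35e-07 to 0.235 over all alternatives). Other immune lists had members past the threshold in the lower direction. The T cell list had 1 higher and 1 lower, the NK cell list 0 higher and 2 lower, and the complement list 0 higher and 1 lower.

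**Figure D3:**
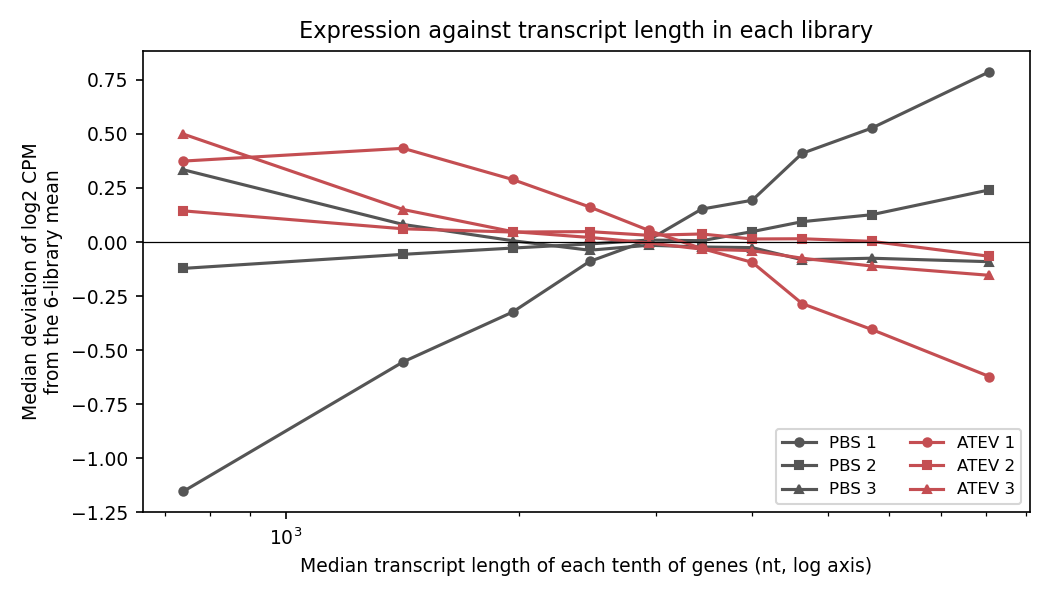
Median deviation of log2 CPM from the 6-library mean (y axis) in 10 equal classes of genes by transcript length (x axis, nt, log scale), 1 line per library, PBS in grey and ATEV in red. The class of shortest transcripts lies at -1.153 in PBS 1 and between -0.122 and 0.499 in the other libraries, and that of the longest at 0.787 in PBS 1 and -0.622 in ATEV 1.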

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

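The length and GC corrections, the table without ribosomal protein genes and Gm42418, the fit without PBS 1 and ATEV 1, and the list tests under total count and upper-quartile scaling were chosen after the data were seen. The numbers of genes higher and lower, 38 and 2 by edgeR, were 40 and 4 with RLE scaling, 42 and 0 with upper-quartile scaling (2741 genes at an unadjusted p under 0.05), 387 and 353 without the low-count filter, 32 and 1 with the stricter filter, 553 and 580 by DESeq2, 34 and 1 by voom, 1681 and 1770 by voom with quality weights, 220 and 85 at the looser threshold, 145 and 43 with length corrected, 255 and 126 with length and GC corrected, and 106 and 25 without both PBS 1 and ATEV 1. With one library left out they ran from 0 to 231 higher and from 0 to 385 lower. Quality weights ran from 0.193 in PBS 1 to 5.139 in PBS 2. Upper-quartile scaling moved the median log2 fold change of all genes by 0.129. The 38 genes kept their direction in every alternative that tested them, and all 38 stayed past the threshold with RLE scaling, without the filter, by DESeq2, with quality weights, without PBS 1 or PBS 3 and under both corrections. Numbers still past were 32 with total count scaling, 37 with upper-quartile scaling, 32 with the stricter filter (which tested 36), 29 by voom, 34 without both PBS 1 and ATEV 1 and 20 without ATEV 2. The causes of these moves were not tested. The stricter filter left 13610 genes to test, while the fits with 1 library left out tested 15076 to 15201, more than the 14731 of the main fit.

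With the replicate number as a block, edgeR called 0 genes higher and 0 lower (1587 at an unadjusted p under 0.05), and 18 lists passed, 17 of them among the 18 of the fit without it. Fibroblasts (-0.33, adjusted p = 0.0517) were not among them and tertiary lymphoid chemokines (0.97, adjusted p = 0.0285) were. The numbers share no stated litter or day, and libraries with the same number did not deviate together (correlations -0.41, -0.24 and -0.1, none best with its own number).

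Of the lists, 18 passed in the main test, 0 with an estimated correlation (camera), 5 by fry, and 13 to 21 with one library left out. None of the 18 medians changed sign, though that of ribosomal protein genes was 0 without both PBS 1 and ATEV 1, and 11 lists passed whichever library was left out. The proliferation median, 0.02, was -0.11 with total count scaling, -0.13 with length corrected, -0.03 with length and GC corrected and -0.33 to 0.34 with one library left out. These were the sign changes among the values described, a choice narrowed after the sign changes had been seen. Over all 25 lists that did not pass, 10 medians changed sign in some alternative, and over all 142 tested genes of the naming rule 5 did (among them Des, Atp2a1, Hba-a1 and Hbb-bt). Of the values of 77 named genes over 20 alternatives, 1237 kept direction and side of the threshold, 234 newly passed and 64 no longer passed.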

Other observations

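All the tests below except those of tissue carried into the samples, of classical-type genes, of leukocytes and of the other splits were chosen after their results, or results close to them, had been seen. The 8 added lists were written after the genes with the largest changes were known.

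Outside the 40 genes past the threshold, the 5 tested genes of the intestine list were higher in ATEV tumors, with a median log2 fold change of 2.56 (camera, adjusted p = 0.000416; adjusted p = 0.13 with an estimated correlation). The list's other members, such as Fabp1, Apoa4, Lct and Muc2, were under the low-count filter and below 1 CPM in both groups. Reg3b, an antimicrobial lectin, stood at 20.3 ± 13.7 CPM in PBS and 120 ± 96.9 CPM in ATEV tumors (SD, n = 3, adjusted p = 0.143, edgeR). The fatty acid binding protein gene Fabp2 had a log2 fold change of 2.81 ± 0.59 (SE, adjusted p = 0.0861). Liver genes had a median of 1.10 over 7 genes (adjusted p = 0.0121; adjusted p = 0.278 with an estimated correlation), and 0.57 with length and GC corrected (adjusted p = 0.0682). Basal-type pancreatic cancer genes had -0.35 over 10 genes (adjusted p = 0.432) and trypsins with acinar genes -0.05 over 3 genes (adjusted p = 0.601). Left out as past the threshold were Fgfbp1 of the basal-type list, at 3.29 ± 0.5 (SE, adjusted p = 0.0444, edgeR), and Try5 of the trypsins, at -2.17 ± 0.31. With length and GC corrected the 3 trypsin and acinar genes had a median of -0.36, with 0 positive (camera, adjusted p = 0.0854). The stomach list kept too few tested genes for a test once those past the threshold were left out.

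Split into 3 and 3 in the 10 possible ways, the 6 libraries gave 38 genes higher and 2 lower in the real split and 0 in each direction in the highest of the others, by edgeR, with up to 2496 genes at an unadjusted p under 0.05. Counting the real one, 1 of the 10 splits gave as many, for higher and for lower genes alike, and 10 splits are too few for a share under 0.05.

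The 38 higher genes had a median log2 fold change of 3.53 and a median transcript length of 1820.5 nt against 3174 nt over all genes. With length taken out the median was 3.24, and with length and GC taken out it was 2.89. All 38 stayed past the threshold in both, which argues against those trends as the whole cause. Broad epithelial genes reached 1.11 at their upper quartile (median 0.40, camera, adjusted p = 0.0121, or 0.365 with an estimated correlation). The lower quartile of the 38 was 3.04, but the 38 were picked by the threshold, and the smallest change among the 40 genes past it was 1.84. The broad epithelial genes thus rose less than the 38, but this cannot exclude a larger share of epithelial cells. Of these 15 epithelial genes 12 were positive. The negative ones were the abundant genes Krt18 at -0.21 ± 0.34, Krt8 at -0.57 ± 0.44 and Cdh1 at -0.74 ± 0.38 (SE), none of them past the threshold. With length and GC corrected the epithelial median was 0.60, with 12 positive and 2 higher past the threshold (camera, adjusted p = 0.00261, or 0.202 with an estimated correlation). Stomach or liver tissue in the samples would bring its other abundant transcripts. The highest ratio of Atp4a, Atp4b, Pgc or Gif to Gkn1, or of Alb to Ttr, was 0.0307 in ATEV tumors. There Alb stood at 4.47 CPM, Ttr at 145 CPM, Pgc at 1.91 CPM and Atp4b and Gif at 0. PBS tumors held Alb at 2.05 CPM and Ttr at 18.6 CPM. These values argue against liver tissue and against stomach tissue that makes those stomach transcripts. Stomach lining that does not make them, and intestine, were not tested for in this way. A hypothesis that stays open is a classical-type program in the tumor cells, since 15 such genes outside the 40 were higher with length and GC corrected (camera, unadjusted p = 0.00247, adjusted p = 0.00433; median 0.50, 8 of 15 positive), though not with an estimated correlation (adjusted p = 0.191), with Agr2 at 3.12 ± 0.60 (SE, uncorrected, adjusted p = 0.0728). The regulators Gata6 and Hnf4a, at 0.17 ± 0.32 and -0.73 ± 0.48, did not pass, and an effect of ATEV through a small subset of cells may equally account for the genes and was not tested.

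The MHC class I and both interferon lists kept at least 0.79 of their medians with length or with length and GC corrected (adjusted p up to 2.45e-06, although none of the fixed lists passed in the fit with both corrected and an estimated correlation, the lowest adjusted p being 0.503), which argues against those trends as the whole cause, although single members such as B2m went from 1.40 to 0.20. The MHC class II list kept 0.79 with both corrected (adjusted p = 0.00152) but 0.49 with length alone corrected (adjusted p = 0.00311), and Ctss went from 1.04 to 0.27 with both, so how much of its median the trends account for cannot be told apart from a change in these genes. Without PBS 1 the 4 lists kept at least 0.8 of their medians (adjusted p up to 3.48e-06), which argues against that library alone. Leaving out ATEV 3 gave the lowest medians with 1 library left out. They were 1 for MHC class I, 0.98 for class II, 0.77 for interferon-gamma and 0.97 for type I (camera, adjusted p up to 0.000391). A larger share of leukocytes cannot be told apart from a response within cells, since the broad leukocyte genes had a median of 0.59 (16 of 20 positive, camera, adjusted p = 0.00118; adjusted p = 0.0919 with an estimated correlation), below the 1.43 of the MHC class I list, with an upper quartile of 1 above the lower quartile of that list, 0.67. The effect of ATEV itself remains open.

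For the lower lists, the smaller share of the median kept under the length correction and the length and GC correction was 0.65 for the endothelial list (adjusted p up to 0.0048) and 0.74 for the mesenchymal and EMT list (adjusted p up to 0.00209, none under 0.503 with an estimated correlation and both corrected), which argues against those trends as the whole cause. The extracellular matrix list kept 0.62 with length corrected and 0.45 with length and GC corrected, and passed in both (adjusted p up to 0.00298), so how much of its median the trends account for cannot be told apart from a change in these genes. Without PBS 1 the 3 lists kept at least 0.7 of their medians (adjusted p up to 0.000882), which argues against that library alone. A loss of stromal and vascular cells in ATEV tumors stays open and was not tested.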
